A study of Homo sapiens with 36 samples.

How the data were processed

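LNCaP and VCaP prostate cancer cells were treated with R1881 or with R1881 and JQ1 for 5, 12 or 24 h. Per the labels, RNA was isolated with the Qiagen RNeasy kit, checked on an Agilent Bioanalyzer, amplified and biotin-labelled with an Illumina TotalPrep kit. There were 12 groups of 3 arrays, 36 in all, and each array was placed in its group by its title. The deposited table holds a linear bead intensity for each of 47323 probes on each array, neither background-corrected nor normalized to judge from its values, and a detection p-value from the authors for each intensity. Per the submitters' processing notes, these came from GenomeStudio 2011.1. The authors' processed values are also intensities. Their sorted values were nearly the same on every array (median relative SD 0.00866%, column medians of 111), and each array's ranks matched its unprocessed intensities, so they are quantile-normalized on a linear scale. They served as an alternative. No column of per-sample values was left unmapped (0 columns). The genome build behind the probe annotation is not given in the sources used here.

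Probes were named through the platform annotation. Of the 47323 probes, 30113 had 1 gene, 8 had several and 17202 had none; probes with several genes or none were not used for genes. The gene identifiers of 30074 probes were found in a RefSeq table of assembly GRCh38.p14, and 0 symbols changed. That table served only for names, for which genes neighbour each other and for gene length.

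Intensities were corrected and normalized with neqc of limma 3.58.1 in R 4.3.3, which subtracts background by normexp with parameters inferred from the detection p-values (770 negative-control beads stand behind them), adds an offset of 16, applies quantile normalization over all 36 arrays and takes log2. Probes with a detection p under 0.01 on at least 3 arrays were kept, 19803 in all, of which 15198 had 1 gene and 4605 had none. For each gene the kept probe of highest mean was used, which left 11439 genes, 2982 of them with more than 1 kept probe. Of 520 called results of named genes, 140 had more than 1 kept probe. In 89 of these all probes were called in the same direction, in 51 some were not called, and in 0 a probe was called in the opposite direction. Among the results described, this concerns EFR3B (1 of 3 probes called), HGD, UBE2C, TP53I3, INSIG1, ELOVL6 and RRM2B (1 of 2), BRWD1 (2 of 4), H2BC5 and the change of PEG10 with time (2 of 3), and AURKA in LNCaP at 24 h (0 of 2 when all probes are adjusted together).

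All 36 arrays entered a single limma model with a mean per group (24 residual and 5.80 prior degrees of freedom), from which 15 contrasts were taken. These were 6 JQ1 effects, 4 time effects under R1881 alone, 3 differences of the JQ1 effect between the lines and 2 differences between 24 and 5 h. P-values are two-sided moderated limma tests, Benjamini-Hochberg adjusted within each contrast, and a gene was called at an adjusted p under 0.05. A probe with no array of an arm above background has only a bound there. The fold is then given as "at least", from the mean of the brighter arm against the mean, over the dim arm's arrays, of the higher of the lowest signal above background and the probe's own signal; no fold is given where this is under 1 or where both arms were below background. Differences between effects that rest on such an arm are given without a size or said to be fitted values.

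There were 23 gene lists, fixed like the design, the named-gene rule and the other ways of processing before the data were examined. They cover androgen-induced and androgen-repressed genes, MYC and ribosome biogenesis genes, BET-inhibitor-induced regulators, histone genes, bromodomain genes, DNA replication and S phase, mitosis, cholesterol synthesis, fatty acid synthesis, the unfolded protein response, p53 targets and apoptosis regulators, immediate early genes, the interferon response, NF-kB and inflammatory genes, hypoxia and glycolysis, ETS factors and ERG-associated genes, lineage transcription factors and receptor cofactors, neuroendocrine genes, and markers of basal epithelium, fibroblasts, leukocytes and endothelium. Lists were tested with camera of limma at a preset correlation of 0.01, which decides the call, and again with an estimated correlation; p-values were adjusted over the lists of a contrast. The endothelial list had 2 tested genes and no camera test. The median, mean and test of a list differed in sign in 15 of 132 tests of JQ1 effects and in 22 of 198 others, of which 0 were called.

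Named genes were, in each JQ1 contrast, the 6 rising and the 6 falling genes of largest absolute log2 fold change among those called whose arms did not overlap, 13 tested genes of 18 chosen beforehand, and up to 4 called members of each list by largest change. For time effects and differences they were 3 in each direction. Unnamed probes and provisional symbols were passed over. With 3 arrays against 3, chance alone separates the arms of 10% of genes. The other 5 of the 18 genes are not reported here.

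Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. Every pair exceeded 0.1 in LNCaP at 12 h (0.164 to 0.226), VCaP at 5 h (0.256 to 0.284) and VCaP at 12 h (0.191 to 0.469), but not in the other 3 JQ1 comparisons, so the model without a block was kept as planned.

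The alternatives were no background correction, median scaling, normalization within each cell line, the authors' processed values, no filter on dim probes, a filter of 18 arrays, the mean of a gene's probes, only the arrays of the line or of the contrast, a replicate block, a trended and robust spread, array weights, and leaving out each array. Leaving out 5 VCaP arrays of weight under 0.5 was added after seeing the data, as were an estimated correlation together with the block or median scaling for lists called only there, and splits with labels exchanged only within replicate numbers. The steps were tested on simulated data with 67, 67 and 66 of 11439 genes changed 1.5-, 2- and 3-fold. In the LNCaP 5 h comparison 35.8%, 74.6% and 97.0% of them were recovered and 4.83% of calls were unchanged genes. In VCaP at 5 h these shares were 52.2%, 82.1%, 98.5% and 24.4%, in VCaP at 24 h 44.8%, 80.6%, 97.0% and 19.6%, and for the difference between the lines at 5 h 8.96%, 53.7%, 90.9% and 4.67%. Among 100 simulated lists of 40 genes, the 1 list shifted by 0.3 on the log2 scale was called and 0 others were. The simulated genes were drawn independently, so this cannot show how often the preset correlation calls lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.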

Results

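Gene expression was measured on 36 Illumina HT-12 BeadChip arrays of 2 prostate cancer cell lines, LNCaP and VCaP. Both lines respond to androgen, and VCaP carries a fusion that places the ETS factor ERG under the TMPRSS2 promoter. Cells were kept for 72 h in medium without phenol red that held 10% charcoal-stripped serum, which is depleted of steroids. They then received 1 nM R1881, a synthetic androgen, or 1 nM R1881 together with 125 nM JQ1, an inhibitor of the BET family of bromodomain proteins, which bind acetylated histones. RNA was taken after 5, 12 or 24 h, which gives 12 groups of 3 arrays. The series design states 3 biological replicates per condition, and the p-values below rest on the spread between them. The median intensity of an array lay between 93.8 and 118, and 13727 to 15885 of the 47323 probes (29.0 to 33.6%) were above background at a detection p under 0.01. Tests covered 11439 genes, and the number of arrays limits the precision.

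The third LNCaP array with R1881 and JQ1 at 24 h carried conflicting labels, with LNCaP in its title and VCaP in its source name. Its correlation across genes was 0.990 to 0.992 with the other 2 arrays of its group and 0.853 to 0.860 with the VCaP arrays. Its ERG level was 4.56 (log2), where the LNCaP arrays spanned 4.37 to 4.91 and the VCaP arrays 5.15 to 7.12, and it was kept in LNCaP.

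The comparison of R1881 with JQ1 against R1881 alone asks which transcripts depend on BET bromodomain proteins in androgen-treated cells. Values below are log2 fold changes ± SE from limma with n = 3 arrays per arm, and p-values are Benjamini-Hochberg adjusted. Each SE uses a single spread per gene, estimated from all groups of both lines together. The SE of a gene is therefore the same in every JQ1 comparison. It may lie below or above what the arrays compared would give alone. A gene that was below background on all arrays of an arm is given as an "at least" fold. The near-identical copies among the histone genes, ORM1 and ORM2, the TUBA3 genes and the TRIM49 family share sequence, so the level of each copy is uncertain.

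After 5 h in LNCaP, JQ1 lowered genes that androgen induces. KLK2, a secreted prostate serine protease, fell by 2.78 ± 0.19 (adjusted p = 8.87e-12), the epithelial ETS factor SPDEF by 2.54 ± 0.19 and the prostate membrane protein SLC45A3 by 1.96 ± 0.18. The acute-phase glycoprotein gene ORM1 was at least 2.56-fold lower. Of 62 androgen-induced genes, 26 fell and 0 rose (28 and 0 adjusted over the list alone), with a median of -0.42 and an adjusted p = 4.65e-05 with an estimated correlation. The growth regulator MYC fell by 2.23 ± 0.28 (adjusted p = 1.25e-06). Among 51 MYC and ribosome biogenesis genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone), including the ribosome biogenesis factors RRS1 (-1.51 ± 0.25) and NOP16 (-1.12 ± 0.21). That list was called with a preset correlation but had an adjusted p = 0.165 with an estimated correlation.

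Histone genes rose in LNCaP at 5 h. H2BC11 gained 1.86 ± 0.32, H4C14 1.73 ± 0.17 and H2BC21 1.32 ± 0.21. In all, 15 of 28 histone genes rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.80 and an adjusted p = 0.00391 with an estimated correlation. Of 15 regulators known to respond to BET inhibitors, 8 rose and 0 fell (11 and 1 adjusted over the list alone, adjusted p = 0.000663 with an estimated correlation). They included the BET family member BRD2 (0.94 ± 0.12) and the growth arrest gene GADD45A (1.14 ± 0.19). Immediate early genes rose for 7 of 22, with 0 falls (7 and 0 adjusted over the list alone), among them ATF3 (1.89 ± 0.27) and JUN (1.62 ± 0.29), both stress-responsive transcription factors; this call had an adjusted p = 0.0559 with an estimated correlation. Of 19 cholesterol synthesis genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). That gene was INSIG1, a feedback regulator of sterol synthesis (1.11 ± 0.33), whose adjusted p became 0.128 without the R1881 array of replicate 1 (0.99). Its call also ended without each of 4 other arrays, without a filter on dim probes and with the mean of its probes.

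Outside the lists, the secreted neuronal pentraxin gene NPTX2 was at least 2.70-fold higher, the poly(A) polymerase gene TENT5C gained 2.02 ± 0.26 and the metalloproteinase gene ADAMTS1 fell by 2.95 ± 0.45. In total, 1011 genes were called at 5 h in LNCaP, 437 that rose and 574 that fell, 722 of them with a fold of at least 1.5. The count was 1597 when only the LNCaP arrays entered the model, 1839 with array weights and 666 without the R1881 and JQ1 array of replicate 1.

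At 12 h in LNCaP the androgen-induced and MYC lists fell. KLK2 fell by 2.51 ± 0.19, SPDEF by 2.28 ± 0.19, and ORM1 was at least 8.73-fold lower. Of 62 androgen-induced genes, 41 fell and 0 rose (45 and 0 adjusted over the list alone; median -0.88, adjusted p = 3.11e-06 with an estimated correlation). MYC fell by 2.03 ± 0.28, and 32 of 51 MYC and ribosome biogenesis genes fell with 0 rising (40 and 0 adjusted over the list alone; median -0.65, adjusted p = 0.0053 with an estimated correlation), NOP16 by 2.01 ± 0.21 and RRS1 by 1.70 ± 0.25. Histone genes rose for 21 of 28 with 0 falls (23 and 0 adjusted over the list alone; median 1.06, adjusted p = 0.00398 with an estimated correlation), H2BC11 by 2.54 ± 0.32. Of the 15 BET-inhibitor-induced regulators, 6 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.00791 with an estimated correlation), including TXNIP, an inhibitor of thioredoxin (2.17 ± 0.30), and HEXIM1, an inhibitor of the elongation kinase P-TEFb (at least 1.51-fold).

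The unfolded protein response list split at 12 h in LNCaP, with 3 of 25 genes rising and 10 falling (4 and 12 adjusted over the list alone; median -0.30), and had an adjusted p = 0.27 with an estimated correlation. The endoplasmic reticulum transcription factors CREB3L4 (-2.91 ± 0.18) and XBP1 (-1.23 ± 0.13) were lower, and the stress genes ATF3 (1.43 ± 0.27) and DDIT4 (1.28 ± 0.25) higher. The cytoskeletal regulator DPYSL3 was at least 4.07-fold and the membrane scaffold gene EFR3B at least 4.13-fold higher, the latter by 1 of its 3 probes. The call covered 2233 genes, 1135 that rose and 1098 that fell, 1476 of them with a fold of at least 1.5.

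At 24 h in LNCaP, ACP3, which encodes prostatic acid phosphatase, was at least 40.5-fold lower with JQ1, from a mean log2 intensity of 10.78 to 4.76, below background on all 3 arrays. KLK2 fell by 3.05 ± 0.19, MYC by 2.57 ± 0.28, KLK3, the prostate-specific antigen gene, by 1.30 ± 0.27, and TMPRSS2, a membrane serine protease gene, by 1.47 ± 0.33. The cyclin gene CCND1 fell by 0.89 ± 0.13. Of 62 androgen-induced genes, 31 fell and 5 rose (33 and 8 adjusted over the list alone; median -0.57, adjusted p = 0.00131 with an estimated correlation), while FKBP5, a member of the same list, was at 0.25 ± 0.19 (adjusted p = 0.383). Among 51 MYC and ribosome biogenesis genes, 30 fell and 0 rose (32 and 0 adjusted over the list alone; median -0.51, adjusted p = 0.0361 with an estimated correlation), including the folate transporter SLC19A1 (-1.72 ± 0.21) and spermidine synthase SRM (-1.29 ± 0.14).

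The rises of histone genes and BET-inhibitor-induced regulators were also called in LNCaP at 24 h. Histone genes rose for 20 of 28 with 1 fall (22 and 2 adjusted over the list alone; median 0.98, adjusted p = 0.0257 with an estimated correlation), H2BC11 by 1.97 ± 0.32 and H2BC21 by 1.77 ± 0.21. Of 15 BET-inhibitor-induced regulators, 8 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 0.00694 with an estimated correlation), TXNIP by 2.00 ± 0.30 and BRD2 by 0.96 ± 0.12. The secreted protease inhibitor SERPINE2 gained 2.98 ± 0.21, the neuronal tubulin TUBB3 2.50 ± 0.18, and the growth factor carrier IGFBP3 3.40 ± 0.71, above background on 2 of 3 arrays with R1881 alone. The androgen-repressed transcriptional coregulator CITED2 gained 2.15 ± 0.21.

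DNA replication genes fell at 24 h in LNCaP for 14 of 40 with 0 rises (16 and 0 adjusted over the list alone; median -0.45, adjusted p = 0.625 with an estimated correlation). The replication licensing factor CDT1 was at least 1.73-fold lower, and the helicase component CDC45 fell by 1.77 ± 0.40 with 2 of 3 JQ1 arrays above background. In the mitosis list 2 of 40 fell and 0 rose (1 and 0 adjusted over the list alone; median -0.56, adjusted p = 0.694 with an estimated correlation). They were the ubiquitin-conjugating enzyme UBE2C (-1.45 ± 0.40) and the kinase AURKA (-1.10 ± 0.41), whose adjusted p became 0.102 (-0.98) and 0.282 (-0.72) without the R1881 and JQ1 array of replicate 1. The call of AURKA also ended without each of 4 other arrays and without background correction, and that of UBE2C with the mean of its probes. Unfolded protein response genes rose for 3 of 25 and fell for 6 (3 and 7 adjusted over the list alone; median -0.25, adjusted p = 0.365 with an estimated correlation); without the array of conflicting labels the preset test gave an adjusted p = 0.0722. CREB3L4 fell by 2.58 ± 0.18. Of 20 p53 targets and apoptosis regulators, 6 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.31, adjusted p = 0.204 with an estimated correlation), with TP53I3, an oxidoreductase gene induced by p53, at least 1.91-fold higher. Immediate early genes rose for 7 of 22 and fell for 2 (8 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.365 with an estimated correlation), JUN by 1.76 ± 0.29. In total 2910 genes were called, 1516 that rose and 1394 that fell, 1897 of them with a fold of at least 1.5.

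**Figure D1:**
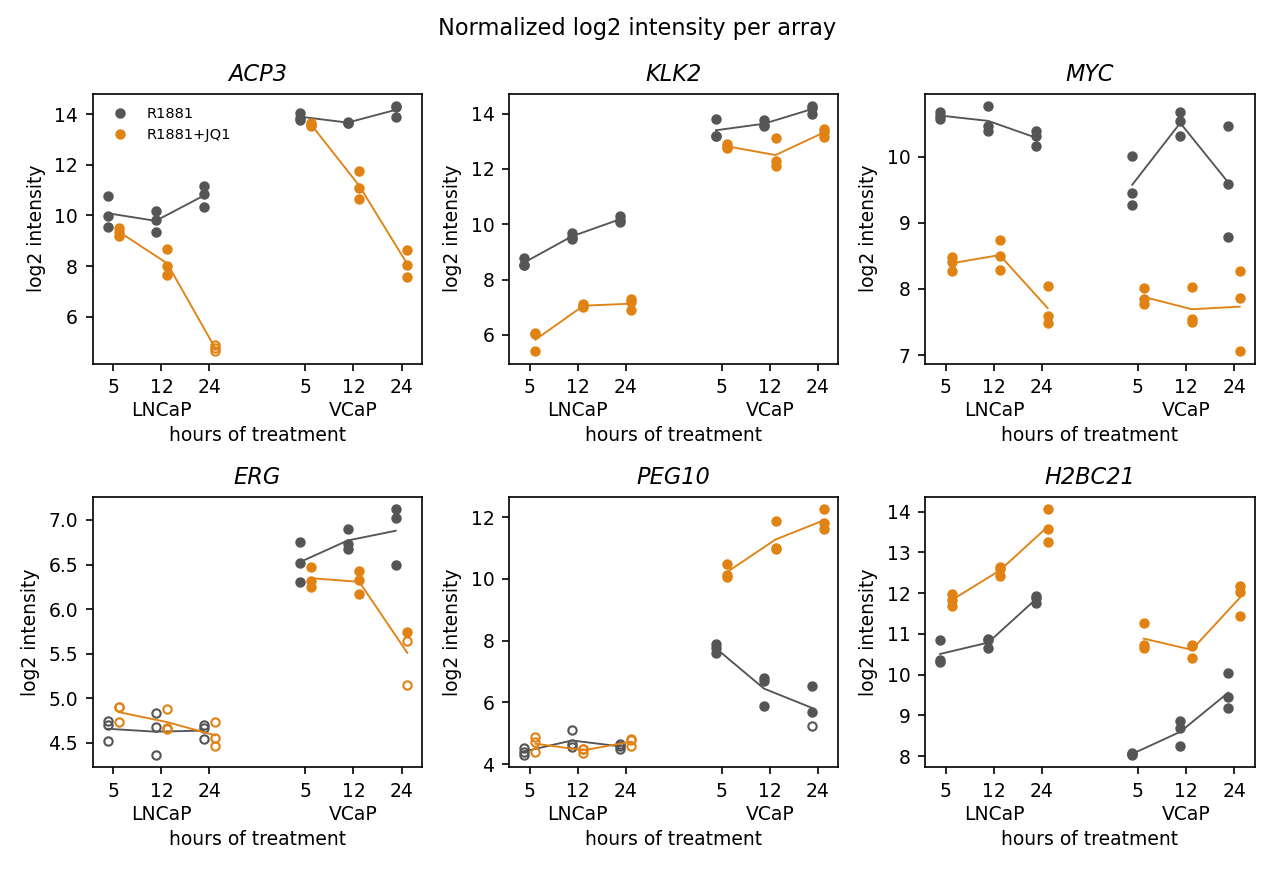
Normalized log2 intensity (vertical axis) of ACP3, KLK2, MYC, ERG, PEG10 and H2BC21 on each of the 36 arrays at 5, 12 and 24 h (horizontal axis) in LNCaP and VCaP, with R1881 alone in grey and R1881 with JQ1 in orange. Each point is an array, open where the probe was not above background, and lines join group means; at 24 h ACP3 was at 10.78 and 4.76 in LNCaP and at 14.17 and 8.08 in VCaP.

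In VCaP at 5 h, NPTX2 gained 4.12 ± 0.19 with JQ1 and EFR3B was at least 8.13-fold higher by 1 of its 3 probes. The heparan sulfate epimerase gene GLCE gained 2.93 ± 0.15. The keratin gene KRT73 was at least 6.88-fold and the anion exchanger gene SLC26A3 at least 3.25-fold lower. SPDEF fell by 1.86 ± 0.19, MYC by 1.69 ± 0.28 and TMPRSS2 by 1.27 ± 0.33. Of 62 androgen-induced genes, 25 fell and 0 rose (26 and 0 adjusted over the list alone; median -0.41, adjusted p = 0.000369 with an estimated correlation), including the elongation factor EAF2 (-2.43 ± 0.24) and ORM2 (-3.95 ± 0.30, above background on 2 of 3 JQ1 arrays). FAM107A, an actin-associated protein gene, fell by 2.70 ± 0.23.

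Histone genes rose in VCaP at 5 h for 21 of 28 with 0 falls (21 and 0 adjusted over the list alone; median 1.32, adjusted p = 0.000369 with an estimated correlation), H2BC5 by 2.88 ± 0.19 and H2BC21 by 2.83 ± 0.21. Of 15 BET-inhibitor-induced regulators, 8 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.96, adjusted p = 0.000369 with an estimated correlation), including GADD45A (2.25 ± 0.19) and the neuronal serpin SERPINI1 (1.55 ± 0.27). Immediate early genes rose for 11 of 22 with 0 falls (14 and 0 adjusted over the list alone; median 0.56, adjusted p = 0.00742 with an estimated correlation), JUN by 1.61 ± 0.29, EGR1 by 1.48 ± 0.26 and IER5 at least 2.86-fold. CDKN1A, the p21 cell-cycle inhibitor, rose by 1.18 ± 0.18. Hypoxia and glycolysis genes rose for 9 of 24 and fell for 2 (10 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.421 with an estimated correlation), including the prolyl hydroxylase subunit P4HA1 (1.40 ± 0.16) and the aldolase ALDOC (1.22 ± 0.12). In the mitosis list 5 of 40 fell and 0 rose (0 and 0 adjusted over the list alone; median -0.72, adjusted p = 0.562 with an estimated correlation). Among them were the centromeric histone CENPA (-1.29 ± 0.44) and the spindle protein PRC1 (-1.19 ± 0.36). Without the R1881 and JQ1 array of replicate 2, on which the mitosis list deviated from its group mean by -0.78 on the log2 scale, their adjusted p became 0.272 (-0.77) and 0.158 (-0.79). Both calls also ended with only the VCaP arrays and without the R1881 array of replicate 1 or 2.

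At 12 h in VCaP, the imprinted gene PEG10, derived from a retrotransposon, gained 4.82 ± 0.25, and EFR3B was at least 10.7-fold higher. The cell-cycle inhibitor CDKN1C (p57) gained 3.01 ± 0.28, and SH3GL2, an endocytosis gene, was at least 6.73-fold higher. SLC26A3 was at least 6.88-fold and the fructose transporter gene SLC2A5 at least 7.59-fold lower, and NWD1 fell by 3.65 ± 0.31. Histone genes rose for 24 of 28 with 0 falls (25 and 0 adjusted over the list alone; median 1.59, adjusted p = 0.00144 with an estimated correlation), H4C14 by 2.73 ± 0.17. Of 15 BET-inhibitor-induced regulators, 11 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.84, adjusted p = 0.00125 with an estimated correlation).

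MYC fell by 2.81 ± 0.28 in VCaP at 12 h, and 27 of 51 MYC and ribosome biogenesis genes fell with 0 rising (31 and 0 adjusted over the list alone; median -0.49, adjusted p = 0.0682 with an estimated correlation), NOP16 by 2.17 ± 0.21. Androgen-induced genes fell for 26 of 62 and rose for 9 (27 and 10 adjusted over the list alone; median -0.27, adjusted p = 0.103 with an estimated correlation), ACP3 by 2.50 ± 0.29 and KLK2 by 1.13 ± 0.19. DNA replication genes rose for 13 of 40 with 0 falls (13 and 0 adjusted over the list alone; median 0.44, adjusted p = 0.667 with an estimated correlation), among them the chromatin assembly subunit CHAF1B (1.17 ± 0.24) and the cohesion factor DSCC1 (1.07 ± 0.15). The replicates of that list spread widely. For replicates 1, 2 and 3 it deviated from its group mean by 0.37, -0.32 and -0.04 with JQ1, and by 0.22, -0.19 and -0.04 with R1881 alone. Of 20 p53 targets and apoptosis regulators, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.186 with an estimated correlation), including RRM2B, a p53-induced ribonucleotide reductase subunit (1.26 ± 0.17). Immediate early genes rose for 10 of 22 with 0 falls (10 and 0 adjusted over the list alone; median 0.41, adjusted p = 0.0682 with an estimated correlation). Of 14 fatty acid synthesis genes, 5 fell and 0 rose (8 and 1 adjusted over the list alone), the elongase ELOVL6 by 1.61 ± 0.26 with 1 of 3 JQ1 arrays above background and the citrate lyase ACLY by 1.09 ± 0.20. That list had an adjusted p = 0.0526 with the preset correlation, 0.0354 with the replicate number as a block, 0.0473 with median scaling, and an adjusted p = 0.541 with an estimated correlation.

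At 24 h in VCaP, PEG10 gained 6.07 ± 0.25, from a mean of 5.82, where 2 of 3 arrays were above background, to 11.89. ACP3 fell by 6.09 ± 0.29, from 14.17 to 8.08, and the myosin-binding protein gene MYBPC1 by 5.29 ± 0.22, above background on 1 of 3 JQ1 arrays. ERG fell by 1.37 ± 0.16, from 6.88 to 5.51, with 1 of 3 JQ1 arrays above background. KLK3 was at least 4.43-fold lower, TMPRSS2 fell by 2.33 ± 0.33, MYC by 1.87 ± 0.28 and KLK2 by 0.85 ± 0.19. The replicates of TMPRSS2 and MYC spread widely here, with SDs of 0.98 and 0.84 with R1881 alone and 0.68 and 0.62 with JQ1. Their SEs, from the spread shared by all groups, do not reflect this. CDKN1C gained 3.47 ± 0.28, SERPINE2 3.36 ± 0.21, CDKN1A 1.55 ± 0.18 and HES6, a transcriptional repressor gene of the androgen-repressed list, 2.76 ± 0.15.

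Histone genes rose in VCaP at 24 h for 26 of 28 with 0 falls (27 and 0 adjusted over the list alone; median 2.02, adjusted p = 0.000311 with an estimated correlation), H4C14 by 3.04 ± 0.17. Of 15 BET-inhibitor-induced regulators, 13 rose and 0 fell (13 and 0 adjusted over the list alone; median 1.05, adjusted p = 9.09e-05 with an estimated correlation). Immediate early genes rose for 13 of 22 with 0 falls (13 and 0 adjusted over the list alone; median 0.78, adjusted p = 0.0112 with an estimated correlation), FOS at least 2.42-fold and JUN by 1.98 ± 0.29. ETS factors and ERG-associated genes fell for 8 of 14 and rose for 2 (8 and 2 adjusted over the list alone; median -0.80, adjusted p = 0.00711 with an estimated correlation), the phospholipase PLA1A by 2.99 ± 0.25 with 2 of 3 JQ1 arrays above background and the secreted protein CRISP3 by 1.88 ± 0.28.

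The androgen-induced list went both ways in VCaP at 24 h, with 25 of 62 falling and 13 rising (25 and 13 adjusted over the list alone; median -0.33, adjusted p = 0.173 with an estimated correlation). MYC and ribosome biogenesis genes fell for 24 of 51 with 0 rises (24 and 0 adjusted over the list alone; median -0.36, adjusted p = 0.118 with an estimated correlation). Unfolded protein response genes rose for 14 of 25 and fell for 3 (16 and 3 adjusted over the list alone; median 0.59, adjusted p = 0.118 with an estimated correlation), the chaperone HSPA5 by 1.33 ± 0.16, while CREB3L4 fell by 1.56 ± 0.18. Of 20 p53 targets and apoptosis regulators, 8 rose and 1 fell (9 and 1 adjusted over the list alone; median 0.32, adjusted p = 0.118 with an estimated correlation).

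In VCaP 2325 genes were called at 5 h (1153 rose, 1172 fell), 3455 at 12 h (1766 and 1689) and 3421 at 24 h (1666 and 1755); 1609, 2371 and 2382 of them had a fold of at least 1.5. Replicates spread more in VCaP, with a median SD per gene of 0.195 to 0.214 against 0.143 to 0.165 in LNCaP, and the model shares a single spread between the lines. In data simulated with these spreads, 24.4% of the genes called at 5 h and 19.6% of those called at 24 h in VCaP were unchanged. When only the VCaP arrays entered the model, these shares were 6.11% and 2.4%. Only 67, 67 and 66 of 11439 simulated genes were changed, far fewer than were called on the real arrays. Such shares depend on how many genes change, so they are not estimates for the real counts above. With only the VCaP arrays the counts were 1580, 2660 and 2545, and with only the 6 arrays of each comparison 1017, 2145 and 2239.

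**Figure D2:**
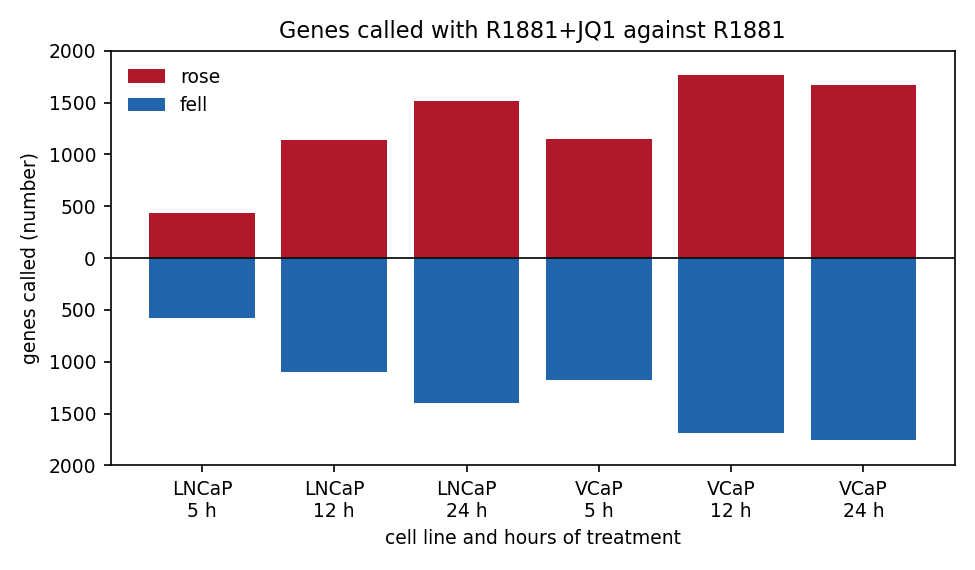
Number of genes called with R1881 and JQ1 against R1881 alone (vertical axis) in each cell line at 5, 12 and 24 h (horizontal axis), with genes that rose above 0 and genes that fell below 0. The bars show 437 risers and 574 fallers in LNCaP at 5 h. In VCaP they show 1766 and 1689 at 12 h and 1666 and 1755 at 24 h.

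**Figure D3:**
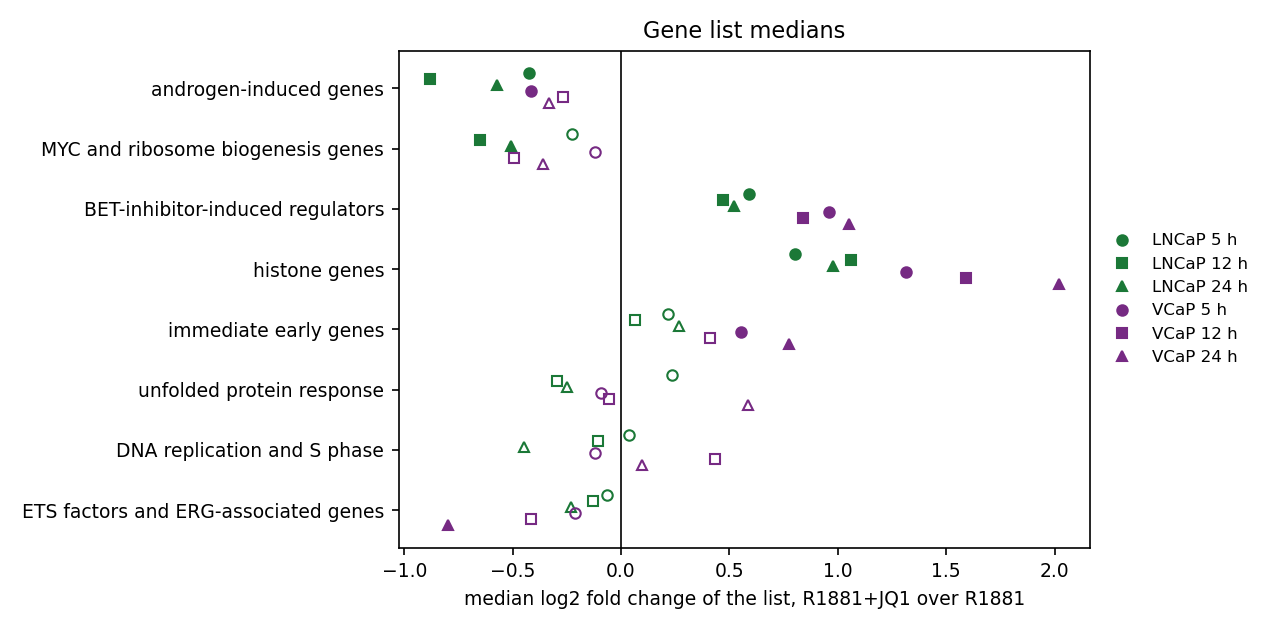
Median log2 fold change with JQ1 (horizontal axis) of 8 gene lists in the 6 comparisons, with LNCaP in green and VCaP in purple. Filled points were called with an estimated correlation; the histone medians run from 0.80 to 2.02 and the androgen-induced medians from -0.88 to -0.27.

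Many genes responded to JQ1 in the same direction in both lines. MYC, GADD45A, JUN, H2BC11, SERPINE2 at 24 h and ACP3 at 24 h were called in the same direction in both. At 5, 12 and 24 h, 275, 702 and 741 genes rose in both lines, where independent lists of these sizes would share 44.0, 175 and 221. In the same order, 282, 611 and 716 fell in both, against 58.8, 162 and 214. The comparisons of the 2 lines share no arrays, but the spread of each gene is estimated from both lines together. A gene of low spread is therefore more readily called in both, and the numbers for independent lists may be too low a baseline. Of the 569, 1335 and 1529 genes called in both, 97.9%, 98.4% and 95.3% changed in the same direction. The Pearson correlation of the log2 fold changes across the 11439 genes was 0.52, 0.58 and 0.53, where genes are not independent replicates. In all 6 comparisons 137 genes rose and 107 fell.

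**Figure D4:**
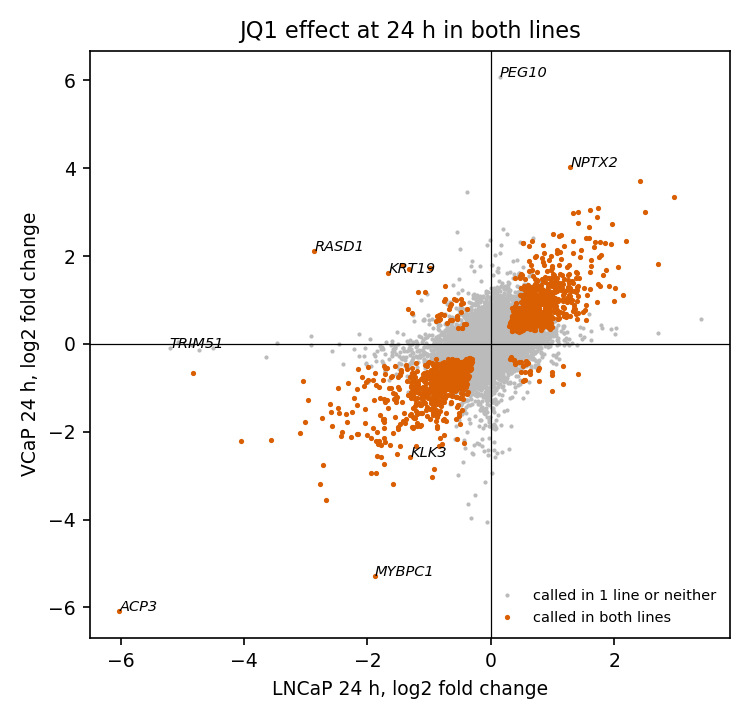
Log2 fold change with JQ1 at 24 h in LNCaP (horizontal axis) and VCaP (vertical axis); each point is a gene, orange where it was called in both lines. PEG10 and TRIM51 lie near 0 in LNCaP and VCaP respectively, ACP3 is plotted below -6 in both, and KRT19 and RASD1, both chosen after their values were seen, were lower in LNCaP and higher in VCaP.

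The response to JQ1 also differed between the lines, tested as the VCaP effect minus the LNCaP effect. At 5 h HES6 was higher by 2.60 ± 0.21 in VCaP relative to LNCaP. EFR3B was also higher and KRT73 lower, without a size, since 0 of 3 VCaP arrays of an arm were above background. KLK2 fell less in VCaP, by a difference of 2.20 at 5 h and 2.20 at 24 h. Its mean log2 intensity with R1881 alone at 24 h was 10.18 in LNCaP and 14.16 in VCaP. CCND1 differed by 1.10 and 1.40, since it was lower with JQ1 in LNCaP and higher in VCaP. That rise was not called with only the arrays compared. At 12 h the RAS-related gene RASD1 differed by 4.16 ± 0.59, with -2.19 in LNCaP and 1.97 in VCaP. Several of the largest differences concern genes without signal in a line. PEG10, FAM107A, KRT73 and the acyl-CoA synthetase gene ACSL5 were above background on 0 of 18 LNCaP arrays, and MYBPC1 on 3. TRIM49D1 was above background on 0 of 18 VCaP arrays and TRIM51 on 7.

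The test of the difference between the lines called 396 genes at 5 h (258 higher in VCaP, 138 lower), 734 at 12 h (384 and 350) and 1071 at 24 h (548 and 523). The count at 5 h was 219 with only the arrays compared, and at 24 h it was 1753 with array weights. Androgen-induced genes were lowered less in VCaP at 12 h, where 16 of 62 differed upward and 0 downward (26 and 0 adjusted over the list alone; median difference 0.52, adjusted p = 0.0014 with an estimated correlation). At 24 h 15 differed upward and 3 downward (21 and 3 adjusted over the list alone; 0.38, adjusted p = 0.019 with an estimated correlation). At 24 h histone genes differed upward for 12 of 28 with 0 downward (15 and 0 adjusted over the list alone; 0.80, adjusted p = 0.019 with an estimated correlation) and unfolded protein response genes for 10 of 25 with 0 downward (14 and 0 adjusted over the list alone; 0.69, adjusted p = 0.017 with an estimated correlation). With the preset correlation 4, 6 and 9 lists were called at 5, 12 and 24 h; those not named here had adjusted p from 0.110 to 0.583, 0.258 to 0.604 and 0.0584 to 0.665 with an estimated correlation.

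The effect of JQ1 also changed between 5 and 24 h. In LNCaP the effect on ACP3, on the homogentisate dioxygenase gene HGD (1 of 2 probes) and on the phosphatase gene INPP4B was lower at 24 h. No size is given, since each was above background on 0 of 3 arrays with JQ1 at 24 h. The falls of SPDEF had receded by 2.05 ± 0.26. In VCaP the effect on PEG10 was higher by 3.59 ± 0.36 and on the retinol dehydrogenase gene RDH10 by 3.11 ± 0.37, and lower on ACP3 (-5.77 ± 0.41) and MYBPC1 (-4.87 ± 0.32). The test called 701 genes in LNCaP (345 higher at 24 h, 356 lower) and 929 in VCaP (392 and 537). The LNCaP count was 1209 with only the LNCaP arrays, 1213 with only the arrays compared, 1486 with array weights and 454 without the R1881 and JQ1 array at 5 h of replicate 2; the VCaP count was 337 with only the VCaP arrays and 231 with only the arrays compared. Unfolded protein response genes moved upward in VCaP for 9 of 25 with 0 downward (12 and 0 adjusted over the list alone; median difference 0.64, adjusted p = 0.036 with an estimated correlation). The other lists called with the preset correlation had adjusted p of 0.244 to 0.655 in LNCaP and 0.0781 to 0.704 in VCaP with an estimated correlation.

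The arrays with R1881 alone show how expression moved with time. No arrays without R1881 are part of this design, so these are changes with time under R1881 and not effects of androgen. In LNCaP from 5 to 12 h the condensin gene NCAPD3 rose by 2.17 ± 0.22, the stress-responsive gene NDRG1 by 2.14 ± 0.15 and the methyltransferase gene GNMT by 1.95 ± 0.23, and the adhesion gene HEPACAM was at least 2.20-fold lower. By 24 h GNMT had risen by 3.44 ± 0.23 and ORM1 by 2.84 ± 0.21, and the metalloreductase gene STEAP4 was at least 5.82-fold higher. GASK1B fell by 2.73 ± 0.36, the kinase inhibitor gene CAMK2N1 by 2.70 ± 0.31 and the DOPA decarboxylase gene DDC by 2.61 ± 0.26.

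Androgen-induced genes rose in LNCaP for 34 of 62 by 12 h with 1 fall (40 and 1 adjusted over the list alone, adjusted p = 1.26e-08 with an estimated correlation) and for 47 by 24 h with 1 fall (50 and 2 adjusted over the list alone; median 1.11, adjusted p = 3.88e-08 with an estimated correlation). Unfolded protein response genes rose for 11 of 25 with 0 falls by 12 h (11 and 0 adjusted over the list alone, adjusted p = 0.0197 with an estimated correlation) and for 15 with 1 fall by 24 h (17 and 1 adjusted over the list alone, adjusted p = 0.00929 with an estimated correlation). By 24 h 11 of 19 cholesterol synthesis genes rose with 0 falls (13 and 1 adjusted over the list alone, adjusted p = 0.00571 with an estimated correlation), 10 of 14 fatty acid synthesis genes rose with 1 fall (10 and 1 adjusted over the list alone, adjusted p = 0.029 with an estimated correlation), and 13 of 24 androgen-repressed genes fell with 2 rises (14 and 3 adjusted over the list alone, adjusted p = 0.0332 with an estimated correlation). DNA replication genes fell for 31 of 40 with 0 rises (34 and 0 adjusted over the list alone, adjusted p = 0.0786 with an estimated correlation) and mitotic genes for 19 of 40 with 0 rises (31 and 0 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation). From 5 to 12 h 423 genes were called (278 rose, 145 fell) and from 5 to 24 h 1928 (946 rose, 982 fell). Median scaling gave 1343 rises and 833 falls by 24 h. The 12 h count was 693 with only the LNCaP arrays and 816 with array weights. Without the R1881 arrays at 5 h of replicate 1 or 2 it was 224 or 249, and without those at 12 h of replicate 2 or 3 it was 254 or 230. The 24 h count was 3042 with array weights.

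In VCaP from 5 to 12 h the LIM protein gene CRIP2 rose by 2.40 ± 0.37 and the zinc finger gene ZNF467 by 2.30 ± 0.18. The matricellular protein gene CCN3 fell by 3.67 ± 0.31, to a level above background on 1 of 3 arrays. RDH10 fell by 3.35 ± 0.26. By 24 h the pepsinogen gene PGC had risen by 3.27 ± 0.26 from a level above background on 1 of 3 arrays, and INSIG1 by 2.77 ± 0.33. RDH10 fell by 5.02 ± 0.26, and CCN3 was at least 14.8-fold lower. The secreted lectin gene REG4 fell by 4.58 ± 0.95, to a level above background on 1 of 3 arrays. Its replicates spread widely, with an SD of 1.81 at 5 h and 1.79 at 24 h. Cholesterol synthesis genes rose for 15 of 19 with 0 falls by 24 h (15 and 0 adjusted over the list alone, adjusted p = 0.0334 with an estimated correlation) and unfolded protein response genes for 17 of 25 with 1 fall (17 and 1 adjusted over the list alone, adjusted p = 0.0334 with an estimated correlation). Androgen-repressed genes fell for 12 of 24 with 0 rises by 24 h (12 and 0 adjusted over the list alone, adjusted p = 0.0612 with an estimated correlation), and DNA replication genes for 30 of 40 with 0 rises (30 and 0 adjusted over the list alone, adjusted p = 0.207 with an estimated correlation). The androgen-induced list was not called at 24 h (adjusted p = 0.605). From 5 to 12 h 2378 genes were called (1194 rose, 1184 fell) and from 5 to 24 h 3508 (1870 rose, 1638 fell). The 12 h count was 1462 with only the VCaP arrays and 869 with only the arrays compared, and the 24 h count was 2164 with only the arrays compared.

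Genes that rose with time under R1881 were often lowered by JQ1. Of 232 genes that rose at least 1.5-fold from 5 to 12 h in LNCaP, 71.6% had a JQ1 effect below 0 at 24 h, and 95 (40.9%) were lowered by JQ1 at 24 h, against 12.2% of all genes, and 27 were raised. In VCaP 58.1% of 809 such genes had an effect below 0, and 253 (31.3%) were lowered, against 15.3% of all genes, and 125 were raised. Of the genes that fell with time, 48.6% in each line had a JQ1 effect above 0; 27 of 107 (25.2%) were raised by JQ1 in LNCaP, against 13.3% of all genes, and 28 were lowered. In VCaP 166 of 755 (22.0%) were raised, against 14.6%, and 161 lowered. The time lists and the JQ1 effect share no arrays, and genes are not independent replicates. Both tests use the same spread of each gene, so a gene called with time may be more readily called with JQ1 than genes at large. Without background correction the counts were 49 of 109 and 136 of 380 for genes that rose and 8 of 34 and 59 of 297 for genes that fell, and with the authors' processed values they were 49 of 106, 136 of 375, 8 of 33 and 58 of 293.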

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

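The test of histone classes, both tests of S phase and the test for signal in VCaP were chosen only after their results were seen. Leaving out the 5 VCaP arrays was a setting chosen after seeing the data, and so were the tests with labels exchanged only within replicate numbers. Results are given here because the effect of JQ1 differed between the lines or between times by a test of the difference itself, or because probes without a gene name responded.

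Histone genes rose with JQ1 in both lines at all times, and the rise was larger in VCaP at 24 h by a median of 0.80. At least 4 histone classes had a called rise in each comparison, so the rise was not confined to a single class. A single transcript read by probes of all classes would also give this, so the count cannot decide on it. At least 14 of 28 genes rose in each comparison under each of 4 normalizations, so the rise does not hang on the choice among them. All 4 bring the arrays compared to a common level, so they cannot test for a shift of all transcripts. A larger share of cells in S phase is not in line with LNCaP at 24 h, where the DNA replication list had a median of -0.45 with 0 rises and 14 falls, although that list's own call was lost with an estimated correlation (adjusted p = 0.625). It stays open in VCaP at 12 h, where that list had a median of 0.44 and its call was lost with an estimated correlation (adjusted p = 0.667). Cross-reading between copies within a class may also contribute, since the deviations of H2B copies from their group means correlated at only 0.138, which neither requires nor excludes it, and a response to BET inhibition that differs between the lines remains an untested hypothesis.

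TRIM48, 3 TRIM49 genes, TRIM51 and GRM5P1 were lower with JQ1 in LNCaP at 24 h and were not called in VCaP at 24 h. In LNCaP TRIM51 fell by 5.20 ± 0.23, and the others, above background on 0 of 3 JQ1 arrays, were at least 8.84- to 18.2-fold lower. In VCaP 11.1% of the 54 values with R1881 alone were above background, all of them from TRIM51 (6 of 9 arrays), so a lack of signal is a candidate explanation for the other 5 genes and stays open for TRIM51. TRIM51 was called as falling in VCaP at 5 h (-0.67, adjusted p = 0.0379; chosen after its values were seen), but the adjusted p was 0.0581 to 0.302 (-0.37 to -0.72) when 1 of the 3 R1881 arrays or the JQ1 array of replicate 1 or 3 was left out, and 0.00748 (-0.92) without the JQ1 array of replicate 2. Whether several of the copies respond or their probes read a single transcript cannot be told apart, since the deviations of the copies correlated at 0.867 over the LNCaP arrays with R1881 and co-regulated copies could give that value too.

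Unfolded protein response genes moved apart between the lines at 24 h, by a median of 0.69 (adjusted p = 0.017 with an estimated correlation). The difference kept its call when each line was normalized by itself (adjusted p = 0.0179 with an estimated correlation), without the array of conflicting labels (0.0274) and without the 5 VCaP arrays of weight under 0.5 (0.0152), which argues against each of these as the whole cause. A difference between the lines in how they respond to JQ1 stays open as an untested explanation, and it may include other differences between their cultures. The list also moved upward in VCaP between 5 and 24 h, by 0.64.

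Androgen-induced genes were lowered less in VCaP, with a median difference of 0.52 at 12 h and 0.38 at 24 h. The fall of KLK2 was smaller in VCaP by 2.20 at 5 h, 1.37 at 12 h and 2.20 at 24 h. With R1881 alone KLK2 was at 8.61, 9.56 and 10.18 (log2) in LNCaP and at 13.40, 13.63 and 14.16 in VCaP. Whether so bright a signal compresses its fall in VCaP was not tested. The effect on BRD2 was lower there, where its rise was called at 24 h only, with differences of -0.71, -0.63 and -0.53, and CCND1 differed by 1.10, 0.74 and 1.40. ATAD2 differed by 1.21 at 12 h, and at 24 h KLK3 differed by -1.28, ERG by -1.32 and CDKN1A by 1.11. ERG was below background on all LNCaP arrays, and KLK3 was above background in VCaP on 2, 2 and 3 of 3 arrays with R1881 alone at 5, 12 and 24 h (mean 7.71 at 24 h) and on 0 of 3 with JQ1 at each time. The differences of both genes are therefore fitted values and not exact sizes. Within VCaP the effect on KLK3 was lower at 24 h than at 5 h by -1.78 and on ERG by -1.19. Of the named genes, many of them chosen for large JQ1 effects, 41 (35.3%), 46 (37.7%) and 61 (43.3%) differed between the lines at 5, 12 and 24 h, against 3.46%, 6.42% and 9.36% of all genes.

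The differences between the lines covered 396, 734 and 1071 genes at 5, 12 and 24 h, and the differences between 24 and 5 h covered 701 genes in LNCaP and 929 in VCaP. The mean JQ1 effect of the lines or times compared was subtracted from each gene before the labels were drawn. Of 100 draws of the JQ1 labels for each, 1 gave as many genes, the real labels. The highest other draws gave 99, 195, 477, 19 and 305, so the real labels stood out at that share for labels exchanged freely. A difference left after the subtraction enters the spread of the other draws, and of the exchanges within replicate numbers below. Their counts may therefore lie below those of arrays without a difference. Same-numbered arrays deviated together in 3 of the 6 JQ1 comparisons. With labels exchanged only within replicate numbers there are 32 arrangements (smallest share 0.0312); 1, the real one, gave as many genes for each difference, and the highest others gave 36, 50, 81, 1 and 92. For the JQ1 effects the 6 arrays allow 10 splits, too few for a share under 0.05. The real splits called 1011, 2233, 2910, 2325, 3455 and 3421 genes and the highest other splits 0, 2, 2, 32, 170 and 234, in the order of LNCaP and then VCaP by time. For the time effects, also with 10 splits, the real values were 423, 1928, 2378 and 3508 and the highest others 1, 1, 55 and 55. In each of these 10 comparisons 1 split, the real one, gave as many. The gene lists called with the preset correlation numbered 6, 5, 9, 6, 7 and 8, and the highest other splits called 7, 10, 10, 10, 10 and 12, with 3, 6, 3, 5, 4 and 4 splits reaching the real number. With an estimated correlation the real splits called 3, 4, 4, 4, 2 and 4 lists and the others 0. For the splits of 6 arrays no effect was subtracted, so the JQ1 or time effect enters the spread of the other splits. Their counts of genes, and of lists with an estimated correlation, may therefore lie below those of arrays without an effect.

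Among 4605 kept probes without a gene name, JQ1 changed 129, 321 and 417 in LNCaP and 309, 513 and 555 in VCaP at 5, 12 and 24 h.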

How the results depend on the processing

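Leaving out 5 VCaP arrays of weight under 0.5 (0.424 to 0.475, all weights 0.424 to 1.89) was chosen only after seeing the data, and so were the tests of lists below that join an estimated correlation with median scaling or the block; the other alternatives were planned. Without these arrays all 15 counts of genes stayed within 1.5 times. Counts with only the line's arrays were 1597 for JQ1 in LNCaP at 5 h, 693 and 1462 for 12 against 5 h in LNCaP and VCaP, and 1209 and 337 for the change of the JQ1 effect with time in LNCaP and VCaP. With only the arrays compared they were 1017, 2145 and 2239 for JQ1 in VCaP, 869 and 2164 for time in VCaP, 219 for the lines at 5 h, and 1213 and 231 for JQ1 by time. Array weights gave 1839 for JQ1 in LNCaP at 5 h, 816 and 3042 for time in LNCaP, 1753 for the lines at 24 h and 1486 for JQ1 by time in LNCaP; these settings change the spread estimate, and why some counts rose and others fell was not tested. Genes that moved with time and were opposed by JQ1 numbered 49, 8, 136 and 59 without background correction and 49, 8, 136 and 58 with the authors' processed values (LNCaP rose and fell, VCaP rose and fell), as fewer genes moved at least 1.5-fold there. With an estimated correlation 3, 4, 2 and 4 lists were called in LNCaP at 5 and 24 h and VCaP at 12 and 24 h; of 132 list results 20 were lost, and with the authors' values 0 changed. MYC genes in VCaP at 5 h were called with median scaling at the preset correlation (adjusted p = 0.0388) but not at an estimated correlation (0.554). Leaving out an array gave 666 to 983 for JQ1 in LNCaP at 5 h, 224 to 405 for 12 against 5 h in LNCaP, 454 to 560 for JQ1 by time in LNCaP, and no other count moved by over 1.5 times. With the replicate number as a block, JQ1 counts were 1185, 2484, 3212, 2614, 3724 and 3721, and the unfolded protein response list in LNCaP at 5 h (adjusted p = 0.0357) and the fatty acid list in VCaP at 12 h (0.0354) were called at the preset but not at an estimated correlation (0.474 and 0.488); of 546 named results 1 was lost and 3 gained. Among the named genes and the 132 list tests of JQ1 effects the block changed no other call, and list tests of time effects and differences were not run with it. IL1RN from 5 to 12 h in LNCaP, at least 1.79-fold lower, reversed to 0.0726 without a filter on dim probes (adjusted p = 0.969), where another probe was chosen. Of the named results 306 of 3899 refits without an array lost the call, and 31 of 546 without the filter. With only the line's arrays 39 of 528 lost it, and with only the arrays compared 54 of 546. The cause was not tested. The BeadChip as a block was not run, since no chip is named. Genes read by a dim probe in an arm, such as KLK3 in VCaP with JQ1, are limited by that probe's signal over background. KLK3 had 1 kept probe.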

Other observations

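The tests of neighbouring genes and of gene length were chosen only after results had been seen; gene lists and named genes follow the rules fixed beforehand.

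Among 29 bromodomain genes the list was not called, with at most 6 rising and 7 falling in a comparison (7 and 7 adjusted over the list alone; lowest adjusted p = 0.198), but ZMYND8, a reader of acetylated histones, fell in all 6 comparisons, from -1.40 ± 0.24 in LNCaP at 5 h to -2.58 ± 0.24 in VCaP at 24 h. BRDT, the testis BET protein, was at least 1.66-fold lower in LNCaP at 12 h, and BRWD1 fell in VCaP by 1.12 ± 0.21 at 5 h and 1.03 ± 0.21 at 24 h. The interferon list (26 genes, at most 6 rising and 7 falling; 6 and 7 adjusted over the list alone; lowest adjusted p = 0.316) was not called, while IRF7, an interferon regulatory factor, rose by 1.58 ± 0.18 in LNCaP and 1.55 ± 0.18 in VCaP at 5 h and the exonuclease gene ISG20 fell by 2.21 ± 0.25 in LNCaP at 24 h. In the NF-kB list (9 genes, at most 3 and 3; 3 and 3 adjusted over the list alone; lowest adjusted p = 0.316) the coactivator BCL3 fell by 1.95 ± 0.19 in VCaP at 12 h. HOXB13, a prostate lineage factor, fell by 1.91 ± 0.25 in VCaP at 12 h and 1.28 ± 0.25 at 24 h, within a list of 16 lineage factors and cofactors that was not called (at most 4 and 4; 4 and 4 adjusted over the list alone; lowest adjusted p = 0.299).

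Neuroendocrine genes rose for at most 5 of 13 and fell for at most 2 (5 and 2 adjusted over the list alone; lowest adjusted p = 0.0621). The glycolytic enzyme gene ENO2 rose by 1.57 ± 0.19 in LNCaP and 1.11 ± 0.19 in VCaP at 24 h, and the granin SCG3 by 0.86 ± 0.12 in VCaP. Androgen-repressed genes rose for at most 5 of 24 and fell for at most 6 (5 and 8 adjusted over the list alone; lowest adjusted p = 0.316), and the cadherin gene CDH2 was at least 1.77-fold higher in VCaP at 24 h. Marker lists of other cell types were not called: basal epithelium (3 genes, at most 1 and 1; 1 and 1 adjusted over the list alone; lowest adjusted p = 0.316), fibroblasts (8 genes, at most 2 and 2; 2 and 2 adjusted over the list alone; 0.603) and leukocytes (5 genes, at most 0 and 1; 0 and 1 adjusted over the list alone; 0.250). Of the leukocyte markers LCP1, an actin-bundling protein gene, fell in both lines at 24 h, by 2.41 ± 0.31 in LNCaP and 2.01 ± 0.31 in VCaP. Of the 2 endothelial markers tested at most 0 rose and 1 fell (0 and 2 adjusted over the list alone), and the TGF-beta coreceptor gene ENG was at least 3.72-fold lower in VCaP at 24 h.

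A hypothesis that neighbouring genes respond together to JQ1 was tested on 10815 neighbouring pairs without a shared symbol start, by the order of genes in assembly GRCh38.p14. That step leaves out only families named alike, so neighbouring histone genes of different classes can remain among the pairs. The correlation of their log2 fold changes across pairs was at least 0.0528 in the 6 comparisons, and the highest values of 1000 shuffles lay between 0.0263 and 0.0352. Related neighbours that remain could give part of this correlation, so it cannot tell weak regional effects from gene families. Pairs are also not independent replicates, and the cause stays open. A hypothesis that longer genes fall more with JQ1 at 5 h found no such relation over 11430 genes. Spearman's rho was -0.00163 in LNCaP and 0.0347 in VCaP at 5 h, 0.0918 and 0.118 at 12 h, and 0.113 and -0.00507 at 24 h.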
